A study of Mus musculus with 21 samples.

How the data were processed

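The data came from 21 single-colour Agilent SurePrint mouse arrays of 62976 spots, of which 3671 were controls, in 7 groups of 3. Per the labels' protocols, CLPs were pooled from mice, with lineage-positive cells partly depleted on beads before sorting. MPPs came from 4 mice per experiment and were stimulated overnight with 50 ng/ml SCF, 5 ng/ml IL-3 and 10 ng/ml IL-6 before infection. Follicular B cells were cultured with an anti-IgM fragment, and their labels name no sort gate. CLP and MPP RNA went through 2 rounds of amplification, and follicular B-cell RNA through linear amplification, of which the label speaks as starting from 1 RNA sample. The sex and age of the mice are not given in the sources used here.

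The values analysed were background-corrected and processed spot intensity values, per the file headers from Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.1. The deposited value table of the series held the same intensity values, linear and not scaled between arrays, for all 21 arrays, with column medians of 155.5 to 255.4 for CLPs, 86.3 to 202.1 for MPPs and 9.30 to 19.3 for follicular B cells, so that the alternative of using it gave the same numbers. From the intensities log2 values were computed and the array's 75th percentile over non-control spots was subtracted; the deposited files held no log2 values. Spots with non-uniformity or population outlier marks were left out and spots of a probe averaged. No spot of a gene probe was saturated (0), and 0 pairs of arrays were identical.

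Probes were given gene names through their RefSeq accession without its version, from an annotation of a later mouse assembly than the one the headers name, so no coordinates were used. Of 55681 probes 26407 were matched, to 20014 gene symbols, and 29274 were not and stayed out of the gene tests. Each gene was represented by its probe with the highest mean over the 21 arrays. Genes were tested where the probe was well above background on at least 3 arrays of the experiment and had at least 2 values per group.

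Groups were compared within each experiment with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table, version 1.17.8, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene passed at an adjusted p under 0.05. The 9 MPP arrays shared 1 estimate of spread, and both B220+ comparisons and the vector comparison share arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures. The 18 gene lists, with 364 entries of which 10 had no named probe (Ighd, Ighm, Ly6c2, Cd68, Clec7a, Hbb-b1, Tpsab1, Mx1, Mx2 and Hspa1b), were written from general knowledge before the data were examined. They were tested as groups with camera, with a preset correlation of 0.01 and, as an alternative, an estimated one. Camera compares the genes of a list with all other genes, not with 0. A list called as shifted up thus lay higher than the other genes and need not have risen. Lists with fewer than 5 measured genes, which were the sex-linked genes, were given as values only.

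Named genes followed a rule fixed before the data were examined. Bach1 and Bach2 are named in every comparison. So are the 10 largest rises and the 10 largest falls among genes that passed, changed at least 2-fold and separated the groups fully; where there were fewer than 5, the genes with the smallest unadjusted p filled the places. Up to 4 members of each list with the smallest p are named as well, and genes known only by an accession, RIKEN or Gm name are counted and not named. Some genes that passed beyond this rule are named as further examples of a list, and a few genes the rule covers are not reported here.

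The labels number the replicates. Whether the numbers pair the arrays was checked by the correlation of their deviations from the group means. It was 0.43, 0.39 and 0.22 for the CLPs, 0.65, 0.41 and 0.30 for the vector comparison and 0.86, 0.72 and 0.53 for the follicular B cells. All were above the limit of 0.1, so there the numbers were taken to pair the arrays. The highest correlation with another number was 0.07 in CLPs, 0.31 between vectors and 0.50 in follicular B cells. Between vectors and in follicular B cells number 1 lay on slide 1 and numbers 2 and 3 on slide 2. A slide effect could give part of the correlation there. In the CLPs the number is also the slide. The median residual SD was 0.503 for CLPs, 0.445 for MPPs and 0.456 for follicular B cells, and 0.328, 0.392 and 0.207 with the replicate as a block.

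On simulated data with 50 genes at each of 4 fold changes, the fit recovered 0% of 2-fold and 24% of 4-fold changes in CLPs and 78% of 16-fold ones; the values were 6%, 52% and 86% for the vector comparison and 0%, 56% and 88% for the follicular B cells. Of the genes called there, 3 of 84, 4 of 118 and 3 of 109 were false. More were false in the B220+ comparisons, with 9 of 122 against control-vector and 10 of 127 against Bach2-vector cells. A list with every gene lowered 2-fold was recovered in all 5 comparisons (smaller or mixed shifts were not simulated), with 0 of the 16 others called. The simulated genes varied independently and without replicate pairs, so that 0 says nothing on lists whose genes vary together. With the measured arrays, wrong splits of the groups called up to 10 lists. Such splits keep part of any real difference between the groups, so that number is not a rate of false calls.

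The alternatives tried were normexp background correction with an offset of 50, quantile normalization, the median of detected probes, no filter and a filter on all arrays, outlier spots kept, the mean of a gene's probes, a variance trend, all 21 arrays in 1 fit, the replicate number or the slide as a block, each array left out in turn, stricter thresholds, and the estimated correlation. Normexp had been planned on mean spot signals; the files hold none, so median spot and background signals were used. Probes without a gene symbol stayed out of the comparisons, as did the control spots.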

Results

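Gene expression was measured on single-colour Agilent mouse arrays in 3 experiments on Bach1 and Bach2, related transcription repressors of the basic leucine zipper family. The first experiment held common lymphoid progenitors (CLPs), bone marrow cells that can give rise to B, T and NK cells, sorted from wild-type (WT) mice and from mice deficient in both factors (DD). In the second, multipotent progenitors (MPPs) of WT mice received a retroviral vector with GFP alone (control vector) or with Bach2 and GFP, and GFP+ cells were sorted after 2 days of multilineage culture. A further Bach2-vector group spent 24 h in that culture and 6 days under B-lineage conditions, after which cells positive for GFP and for B220, a surface marker of B-lineage cells, were sorted. The third experiment held follicular B cells of WT and Bach2-knockout (Bach2KO) mice kept for 24 h with 10 ug/ml of an antibody fragment against IgM, which engages the B-cell receptor. Each of the 7 groups had 3 arrays, 21 in all.

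Signal differed between the experiments. Between 66.8% and 81.5% of spots were well above background on the CLP arrays and between 62.6% and 81.4% on the MPP arrays, against 50.9% to 58.8% on the follicular B-cell arrays, where the 75th percentile of signal was 97.3 on Bach2KO replicate 2 and 194.5 to 357.5 on the other 5 arrays. For arrays, their number limits the precision. The label of the follicular B cells speaks of 1 RNA sample being amplified, and nothing names separate animals for those 3 arrays, so p-values may measure partly technical spread there. Replicate 1 of each genotype differed from the other 2 arrays in Xist, so the 3 did not all hold the same RNA. Differences between groups are given as log2 values ± SE with limma's adjusted p. They rest on n = 3 arrays per group, or on 2 where outlier spots were left out. Levels are given as log2 signal relative to the array's 75th percentile. Where a probe was not well above background on any array of a group, the fold is a lower bound, "at least N-fold". Where it was on 1 of 3, the fold or log2 value given rests mostly on signal near background, and that is said beside it. The gene lists and the rule for the genes named were fixed before the data were examined.

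The Y-linked transcripts Ddx3y and Eif2s3y separated replicate 3 of every MPP group from the rest. Ddx3y stood at 0.82 to 1.59 in replicates 1 and 2 of the 3 groups, and at -9.09, -9.32 and -8.69, not well above background, in replicate 3 of the control-vector, Bach2-vector and B220+ cells. Xist, the transcript that silences an X chromosome in female cells, lay at -2.23, -1.49 and -2.13 in those 3 arrays and at -5.49 to -4.31 in the other 6. In the follicular B cells Xist was above background in replicate 1 only, at -1.49 in WT and -2.32 in Bach2KO cells, against -6.42 and -5.43 in WT and -5.59 and -6.38 in Bach2KO replicates 2 and 3. None of the sex-linked genes passed the test in any comparison, with Eif2s3y at 0.24 ± 0.92 in DD against WT CLPs, 0.42 ± 4.82 between vectors, 0.19 ± 4.82 and -0.24 ± 4.82 in B220+ cells against control-vector and Bach2-vector MPPs, and -0.13 ± 0.34 in follicular B cells.

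Bach2 itself, read by 2 probes, was low in Bach2KO follicular B cells. The brighter probe stood at 3.37 ± 0.27 (SD, n = 3) in WT and -0.39 ± 0.54 in Bach2KO cells, a fall of 13.5-fold (adjusted p = 9.2e-04). The dimmer probe was at least 23.7-fold lower, being above background on 0 of 3 knockout arrays. In CLPs the brighter probe read 2.45 ± 0.98 in WT and 0.33 ± 0.75 in DD cells, with every DD array below every WT array, but the 4.32-fold difference did not pass (adjusted p = 0.999). In MPPs the probes differed. The brighter one read -2.99 ± 0.86 with the control vector and -1.84 ± 0.84 with the Bach2 vector (adjusted p = 0.775). The dimmer one read -7.34 ± 1.13, above background on 1 of 3 arrays, against -2.91 ± 1.44 on 3 of 3, a 21.6-fold difference. In B220+ cells these probes read -3.11 ± 0.86 and -3.89 ± 2.04, and the brighter one did not pass against control-vector (-0.12 ± 0.61, adjusted p = 0.909) or Bach2-vector cells (-1.27 ± 0.61, adjusted p = 0.230). Bach1 read 2.00 ± 0.16 in WT and 1.48 ± 0.82 in DD CLPs (adjusted p = 0.999). It read 1.88 ± 0.39 and 0.88 ± 0.25 in control-vector and Bach2-vector MPPs (adjusted p = 0.857), and 1.03 ± 0.19 and 1.56 ± 0.27 in WT and Bach2KO follicular B cells (adjusted p = 0.615). In B220+ cells Bach1 read 1.27 ± 1.27 (adjusted p = 0.483 against control-vector and 0.689 against Bach2-vector cells). Where the probes lie relative to the deleted parts and to the vector insert is not known, and a probe outside them checks nothing.

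**Figure D1:**
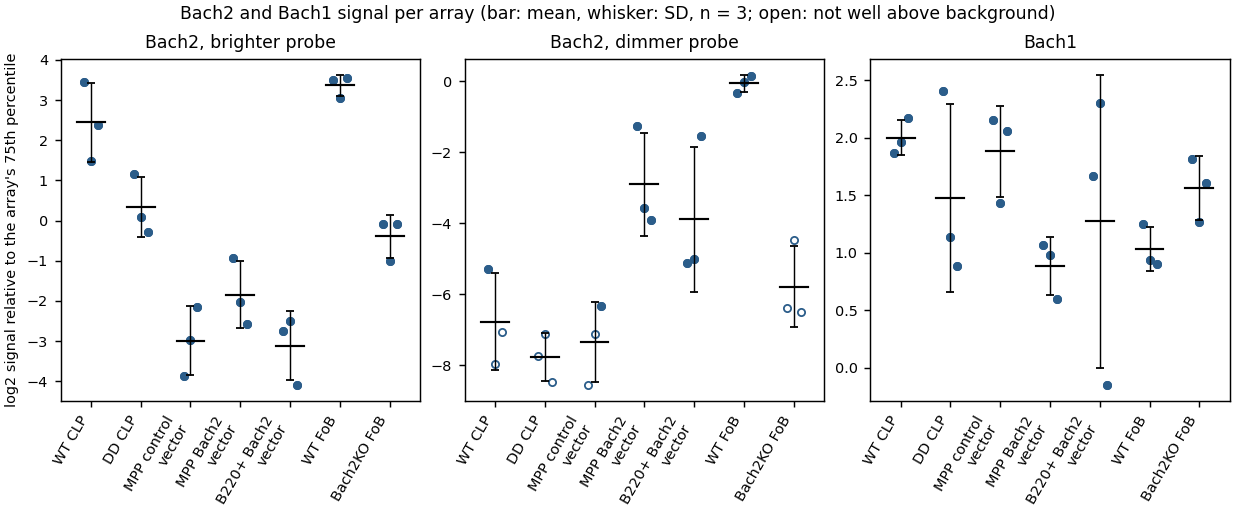
Level of each probe for Bach2 (brighter and dimmer) and for Bach1 on all 21 arrays, as log2 signal relative to the array's 75th percentile, for the 7 groups; points are arrays (open where not well above background), bars the mean and whiskers the SD, n = 3. The brighter Bach2 probe sits at 3.37 in WT and -0.39 in Bach2KO follicular B cells, and the dimmer one at -7.34 with the control vector and -2.91 with the Bach2 vector.

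The CLP comparison asked which transcripts depend on Bach1 and Bach2 together in lymphoid progenitors. One gene of 16462 tested passed. Rspo1, which encodes a secreted activator of Wnt signalling, was 23.3-fold higher in DD CLPs (log2 4.54 ± 0.39, adjusted p = 0.0286, higher in 3 of 3 DD arrays than in every WT array). Its WT level was -5.54 ± 0.19 (SD). Below that, 619 genes had an unadjusted p under 0.05 (334 higher and 285 lower in DD) where 823 would by chance, and 7.91% of genes had all DD arrays on one side of all WT arrays, where chance gives 10%. Both chance values take the arrays as unpaired, whereas the replicate numbers were taken to pair them. With the number as a block 1482 genes had an unadjusted p under 0.05, but 0 passed and Rspo1 had an adjusted p of 0.383 (limma). The genes with the next smallest p failed the correction. Among them Morrbid, a long noncoding RNA that prolongs the life of short-lived myeloid cells, was higher by 3.82 ± 0.44 (adjusted p = 0.143). Sv2c was higher by 8.59-fold (adjusted p = 0.143, above background on 1 of 3 WT arrays). Hacd4 was higher by 2.94 ± 0.43 and Spag1 by 2.13 ± 0.32 (adjusted p = 0.337 each). Klk6 read -3.50 ± 0.42 (adjusted p = 0.223), Gnai1 -3.69 ± 0.62, Snord123 -3.29 ± 0.61, Kcnk10 -2.83 ± 0.55 and Clec4f -2.13 ± 0.44, with adjusted p from 0.419 to 0.682. Klk6, Gnai1, Snord123 and Kcnk10 were each above background on 1 of 3 DD arrays, and Klk6 had values on 2 WT arrays.

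In DD CLPs 4 gene lists shifted as groups, although no member of any list passed the test over all genes (limma, 619 genes at an unadjusted p under 0.05). The interferon-response list lay higher (14 of 17 measured genes, median log2 0.56, adjusted p = 0.00362, but adjusted p = 0.509 with an estimated correlation). Ifit3 read 0.79 ± 0.32 and Oasl1 0.83 ± 0.39. The heme, iron and oxidative-stress list, which holds the classic targets of the Bach factors, lay higher too, with 17 of 24 genes up and a median of 0.32 (adjusted p = 0.0157, and adjusted p = 0.425 with an estimated correlation). Its Hmox1, the heme-degrading enzyme, read 1.66 ± 0.41 (adjusted p = 0.978) and its Gclm, a glutathione-synthesis subunit, 1.91 ± 0.47 (adjusted p = 0.948). Of the 24, 2 were higher and 0 lower when adjusted over the list alone. Early B-lineage genes lay lower in 20 of 27 cases (median -0.16, adjusted p = 0.0157, and adjusted p = 0.554 with an estimated correlation). Pou2af1, a B-cell coactivator, read -2.14 ± 0.49, Vpreb3 -1.27 ± 0.51 and Igll1, a surrogate light chain, -1.25 ± 0.63. NK and innate lymphoid genes had a median of -0.60 with 10 of 18 lower (adjusted p = 0.0157, and adjusted p = 0.425 with an estimated correlation). Rora read -2.25 ± 0.59 and Zbtb16, the regulator of innate-like lymphocytes, -1.58 ± 0.52. Adjusted over the list alone, 0 genes of the interferon, early B and NK lists passed.

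The other lists did not shift in CLPs. Stem and multipotent progenitor genes came closest (adjusted p = 0.0530), with Ly6a, which encodes Sca-1, at 1.97 ± 0.35 and Slamf1 at 1.79 ± 0.38. Of its 19 genes 2 were higher when adjusted over the list alone. It passed upward with a variance trend (adjusted p = 0.0368) and without DD replicate 3 (0.0156) or WT replicate 2 (0.0253) or 3 (0.0232). Of the plasma-cell genes 1, Fkbp11 at 2.62 ± 0.41, was higher when adjusted over the list alone (list adjusted p = 0.321). Cell-cycle genes were higher in 20 of 23 cases (adjusted p = 0.130), and passed without DD replicate 2 (0.0193) or WT replicate 2 (0.0329) or 3 (0.0134). Monocyte genes passed upward without DD replicate 3 (adjusted p = 0.0278) or WT replicate 3 (0.0293), and erythroid genes downward without WT replicate 2 (0.0307). Granulocyte genes had an adjusted p of 0.526 in 19 measured members. Ms4a3 read 2.61 ± 0.82, Ctsg 1.35 ± 0.50 and Elane 1.24 ± 0.47. The list's median over 19 genes, each relative to its own mean, was -1.37, -0.47 and 1.77 in WT replicates 1 to 3 and -0.17, 0.61 and -0.62 in DD. Without WT replicate 3 the list lay higher in DD with a median of 0.76 (adjusted p = 1.39e-06). The adjusted p was 0.321 for mature B, B-cell activation, monocyte and macrophage, dendritic, T-lineage and erythroid and megakaryocyte genes, 0.342 for mast-cell and basophil genes, 0.552 for myeloid regulators and receptors and 0.837 for immediate-early genes. All of these had 0 members passing when adjusted over the list alone. Median, mean and test differed in sign for the myeloid-regulator, granulocyte, T-lineage and immediate-early lists. With the replicate number, which here is also the slide, as a block, 0 genes passed (limma, 1482 at an unadjusted p under 0.05), Rspo1 had an adjusted p of 0.383 and the heme list one of 0.0647. Within slides 1, 2 and 3, each with 1 array per genotype, early B genes had medians of -0.61, 0.19 and -0.0079. With quantile normalization the NK (adjusted p = 0.0566) and heme lists (adjusted p = 0.119) no longer passed, nor did the NK list with a filter on all arrays (median -0.25, adjusted p = 0.0883). Without WT replicate 1 or DD replicate 1 none of the 4 did, the lowest adjusted p being 0.0830 and 0.169.

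The vector comparison asked what added Bach2 does to WT multipotent progenitors within 2 days. Mmp8, the neutrophil collagenase, fell 68.3-fold, Thbs1, an extracellular matrix glycoprotein of platelets and macrophages, 55.9-fold, the macrophage transcription factor Tfec 57.0-fold, Slc7a11, the cystine importer of glutathione synthesis, 53.6-fold, and Srxn1, which repairs oxidised peroxiredoxins, 19.0-fold. Cd83 rose by 109-fold (above background on 1 of 3 control arrays). The chemokine Xcl1 rose by 68.3-fold, the NK receptor gene Klrd1 by 25.5-fold, Gbp4 by 22.3-fold and the lymphocyte homing receptor Ccr7 by 12.0-fold. In all, 305 of 16987 genes passed, 182 higher and 123 lower with Bach2, and each changed by at least 2-fold, the smallest by 2.13-fold. At an unadjusted p under 0.05 there were 1472 genes where chance gives 849, and 14.9% of genes separated the groups fully, where chance gives 10%. These chance values, too, take the arrays as unpaired, although the replicate numbers were taken to pair them.

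Among the largest rises, Cd83 changed by log2 6.77 ± 1.04 (adjusted p = 0.0144, above background on 1 of 3 control arrays) and Upb1 by 5.66 ± 0.48 (adjusted p = 0.00113). Bmp2, a secreted growth factor, rose by 5.27 ± 0.43 (adjusted p = 0.00113) and Igsf5 by 5.07 ± 0.80, both above background on 1 of 3 control arrays, Clca1 by 4.66 ± 0.64 and Khdc1a by 4.59 ± 0.91. Wnt9a, a Wnt ligand, rose at least 16.9-fold (adjusted p = 0.00353). Among the largest falls, Sirpb1b fell by 6.67 ± 0.98 (adjusted p = 0.0113, above background on 1 of 3 Bach2-vector arrays). Rhou, a small GTPase, fell by 6.06 ± 0.51 (adjusted p = 0.00113), and Me1, which makes cytosolic NADPH, fell by 5.82 ± 0.93 (adjusted p = 0.0163). Stfa1 and Cstdc5, cystatin-family protease inhibitors of granulocytes, fell by 5.80 ± 0.75 and dropped by 5.30 ± 0.75, and Lypd6b fell by 5.34 ± 0.88.

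Heme, iron and oxidative-stress genes fell as a group with Bach2. All 25 were lower, 0 rose, 7 fell and 18 did not pass (0 and 8 adjusted over the list alone). They had a median of -0.82 and an adjusted p of 1.38e-16, and 0.00128 with an estimated correlation. No other list of the vector comparison was kept by that test. Gclm fell 9.24-fold (adjusted p = 0.00438) and Gsta4, a glutathione transferase, 4.88-fold (adjusted p = 0.008). Granulocyte genes were lower in 19 of 20 cases with a median of -0.75 (adjusted p = 4.56e-08, and adjusted p = 0.113 with an estimated correlation). Only Mmp8 fell, 0 rose and 19 did not pass, with 4 fallen when adjusted over the list alone. The values were -3.27 ± 0.76 for Chil3, -1.99 ± 0.54 for S100a8 and -1.47 ± 0.40 for Fcnb. Of 23 monocyte and macrophage genes 3 fell, 0 rose and 20 did not pass, with 5 fallen when adjusted over the list alone (adjusted p = 1.16e-04, and adjusted p = 0.222 with an estimated correlation). The complement receptor gene C5ar1 fell at least 6.74-fold, the chemokine Ccl9 5.51-fold and the coagulation factor gene F13a1 19.7-fold. The transcription factor gene Cebpd fell 3.23-fold (adjusted p = 0.0108) and the Fc receptor gene Fcgr3 5.61-fold (adjusted p = 0.0149). Of 24 myeloid regulators and receptors 2 fell, 0 rose and 22 did not pass, with 5 fallen when adjusted over the list alone (adjusted p = 0.00163, and adjusted p = 0.210 with an estimated correlation).

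**Figure D2:**
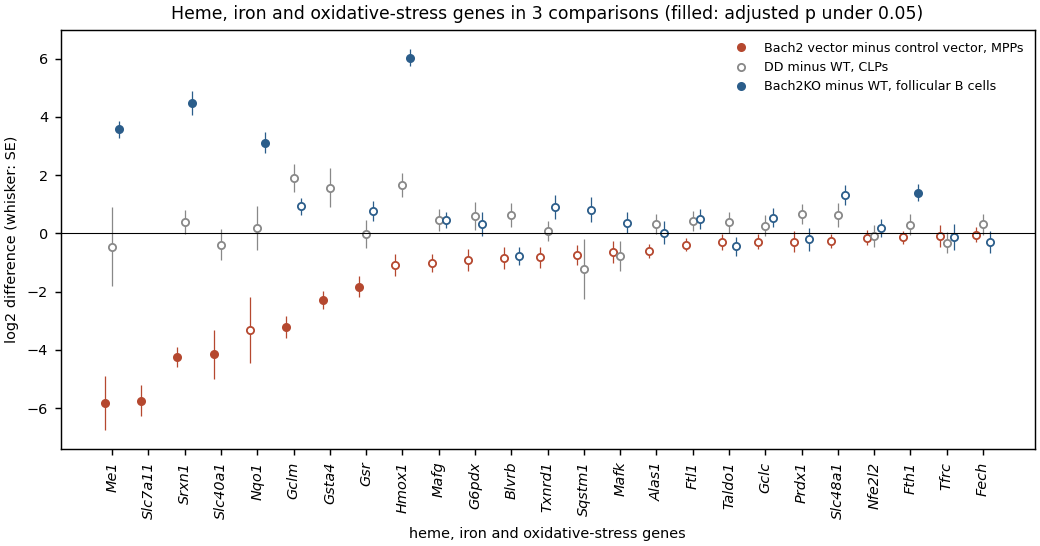
Log2 difference ± SE (n = 3 arrays per group) of the 25 heme, iron and oxidative-stress genes in DD against WT CLPs, Bach2 against control vector in MPPs and Bach2KO against WT follicular B cells; filled points passed limma's test at an adjusted p under 0.05. Srxn1 lies at -4.25 with the Bach2 vector and at 4.49 in Bach2KO cells, where Hmox1 lies at 6.04, and all 25 genes lie below 0 with the Bach2 vector.

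Interferon-response genes rose as a group with Bach2, with 15 of 17 higher and a median of 1.30 (adjusted p = 8.91e-10, and adjusted p = 0.113 with an estimated correlation). Of these 3 rose and 14 did not pass, with 7 risen when adjusted over the list alone. These 3 were the guanylate-binding protein genes Gbp2 and Gbp3, the last by 2.86-fold, and the RNA sensor Ifih1 by 3.45-fold. NK and innate lymphoid genes had a median of 0.85 with 1 of 18 risen, Klrd1 (4.67 ± 0.64, adjusted p = 0.00893), and 4 when adjusted over the list alone (adjusted p = 1.45e-04, and adjusted p = 0.113 with an estimated correlation). Tbx21, which encodes T-bet, read 2.77 ± 0.76 and Il2rb 1.64 ± 0.44. Dendritic-cell genes shifted up with 0 of 17 passing and 3 risen when adjusted over the list alone (adjusted p = 1.45e-04, and adjusted p = 0.113 with an estimated correlation). Clec10a read 1.28 ± 0.30, Id2 1.40 ± 0.34 and H2-Aa 1.45 ± 0.42. Of 20 T-lineage genes 1 rose, Il2ra by 6.19-fold, and 2 when adjusted over the list alone (adjusted p = 0.00940, and adjusted p = 0.281 with an estimated correlation). Gata3 read 1.96 ± 0.45.

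Of 26 early B-lineage genes 3 rose, 0 fell and 23 did not pass, with 6 risen when adjusted over the list alone (median 0.07, adjusted p = 0.00176, and adjusted p = 0.281 with an estimated correlation). Cd72 rose 5.28-fold, Vpreb3 4.08-fold and Foxo1, needed for early B-cell gene expression, 2.40-fold, while Blnk read 2.75 ± 0.65 (adjusted p = 0.0903). Of 19 mature B-cell genes 2 rose, the BAFF receptor gene Tnfrsf13c by 8.98-fold and the repressor Bcl6 by 6.01-fold, and 1 fell (4 and 2 adjusted over the list alone, adjusted p = 0.0136, and adjusted p = 0.174 with an estimated correlation). Of 23 B-cell activation genes 3 rose, Cd83, Ccr7 and Il2ra, and 0 fell (5 and 1 adjusted over the list alone), but the list did not shift (adjusted p = 0.0946). It passed upward with all 21 arrays in 1 fit (adjusted p = 0.0193) and without Bach2-vector replicate 2 (0.00468) or control replicate 1 (0.00580). The plasma-cell list did not shift (adjusted p = 0.580), of whose 18 genes Irf4 rose 7.46-fold and Ell2, a transcription elongation factor, fell 2.85-fold (2 and 3 adjusted over the list alone). Of 14 mast-cell and basophil genes 1 rose, Hdc, which makes histamine, by 5.28-fold, and when adjusted over the list alone 1 rose and 1 fell (adjusted p = 0.569). Over all genes 0 members passed among 19 erythroid and megakaryocyte (adjusted p = 0.351), 18 stem and progenitor (0.750), 23 cell-cycle (0.750) and 14 immediate-early genes (0.0568). Adjusted over the list alone, 1 erythroid gene fell and 1 stem-cell and 1 immediate-early gene rose. The immediate-early list passed upward on the arrays numbered 1 and 2 alone (adjusted p = 0.0201) and without Bach2-vector replicate 2 (0.0173) or 3 (0.0396) or control replicate 1 (0.0253). Median, mean and test differed in sign for the plasma-cell, mast-cell and stem-cell lists.

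With the replicate number as a block Cd40 (adjusted p = 0.0257), Chil3 (0.0461), Tlr2 (0.0481), Mitf (0.0396) and Usp18 (0.0161) passed as well, and Foxo1 (0.0897), Vpreb3 (0.0832) and Khdc1a (0.0781) did not. Slides held both vectors. With the slide as a block 365 genes passed (211 higher, 154 lower). Within slides 1 and 2 the lists had heme medians of -0.93 and -0.68, granulocyte medians of -1.12 and -0.75, an interferon median of 1.24 on slide 1, and early B medians of 0.49 on slide 1 and -0.12 on slide 2. The granulocyte, monocyte, dendritic, NK, heme and interferon lists kept their call in every alternative other than the estimated correlation. Mature B genes lost it without Bach2-vector replicate 1 (adjusted p = 0.318) or control replicate 2 (0.0747), the myeloid regulators without control replicate 1 (0.0760), and early B on slide 2 alone (0.217). On the arrays numbered 1 and 2 alone the T-lineage list (0.0727) and the myeloid regulators (0.0800) lost it, and on slide 2 alone the mature B genes (0.0545). The count of genes was 106 without control replicate 2, 111 without Bach2-vector replicate 3, 124 without control replicate 1. It was 146 and 199 without Bach2-vector replicates 2 and 1, and 189 without control replicate 3, and 163 on the arrays numbered 1 and 2 alone.

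The first B220+ comparison asked how Bach2-vector cells that became B220+ differed from control-vector MPPs, and the groups differ in culture and duration as well as in vector and sort. Dntt, the polymerase that adds bases at immunoglobulin gene joints, rose 140-fold, the B-cell receptor adaptor Blnk 162-fold, the B-lineage marker Ly6d 53.5-fold and the Ets factor Spib 27.3-fold. The chemokine Ccl24 fell by at least 322-fold, the thromboxane synthase gene Tbxas1 by 146-fold and Pf4, platelet factor, by 124-fold. The eosinophil granule protein genes Prg2 and Prg3 rose by 494-fold and by 100-fold, and the basophil protease gene Prss34 by 122-fold. In all, 2056 of 16987 genes passed, 790 higher and 1266 lower in B220+ cells, of which 749 and 1157 by at least 2-fold. With quantile normalization the numbers were 994 higher and 1031 lower, and the median over all genes moved from -0.29 to -0.08.

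Dntt changed by log2 7.13 ± 0.25 (adjusted p = 5.67e-06), Blnk by 7.34 ± 0.65 (adjusted p = 2.99e-04) and Prg2 by 8.95 ± 0.87 (adjusted p = 4.43e-04, above background on 2 of 3 control arrays). Cd2, a lymphocyte adhesion receptor, rose at least 781-fold, Fzd10 at least 84.3-fold, Wnt9a at least 63.8-fold and Slc16a14 at least 56.1-fold, and the interleukin-18 receptor gene Il18r1 rose by 7.95 ± 1.12. Afp, alpha-fetoprotein, fell at least 1359-fold (adjusted p = 7.78e-05). Tfec and Hic1, a transcription repressor, fell by 7.03 ± 0.95 and fell by 7.03 ± 0.49, Slc7a11 fell by 6.59 ± 0.52, and Lypd6b, Scarf1 and Cpne8 were lower by at least 42.8-fold, 35.6-fold and 32.3-fold.

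Of 26 early B-lineage genes 9 rose, 0 fell and 17 did not pass (10 and 2 adjusted over the list alone, median 0.63, adjusted p = 5.99e-07, and adjusted p = 0.135 with an estimated correlation). With the slide as a block the early B median was 1.13 (adjusted p = 4.77e-07), and within slide 1 it was 1.27. The interleukin-7 receptor gene Il7r rose 31.8-fold. Pax5 and Cd79a, which mark B-lineage commitment, read -0.86 ± 0.30 and -0.38 ± 0.63 (adjusted p = 0.0934 and 0.708), and Ebf1 was too dim to be tested. These 4 were chosen after their values were seen. Of 19 mature B-cell genes 5 rose, such as H2-Ob by 13.5-fold, Bcl6 by 10.9-fold and Bank1 by 10.1-fold, and 2 fell, among them Cd180 by 11.8-fold (6 and 2 adjusted over the list alone, adjusted p = 2.18e-04, and adjusted p = 0.104 with an estimated correlation). Heme, iron and oxidative-stress genes shifted down, with 12 of 25 fallen and 0 risen (15 and 0 adjusted over the list alone, median -1.26, adjusted p = 1.21e-05, and 0.0297 with an estimated correlation). Srxn1 fell 76.2-fold and Gclm 22.8-fold.

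**Figure D3:**
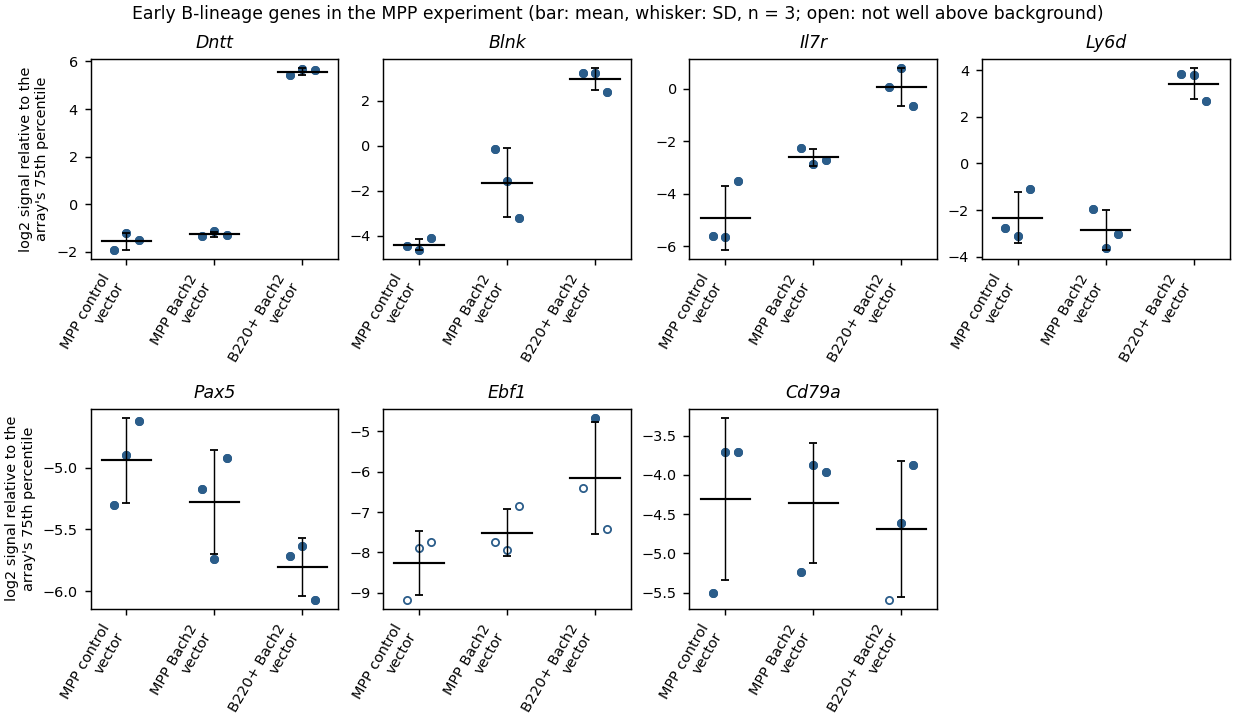
Level of Dntt, Blnk, Il7r, Ly6d, Pax5, Ebf1 and Cd79a in control-vector, Bach2-vector and B220+ cells, as log2 signal relative to the array's 75th percentile; points are arrays (open where not well above background), bars the mean and whiskers the SD, n = 3. Dntt and Blnk lie higher in all 3 B220+ arrays than in the control arrays, by 7.13 and 7.34, while Pax5 and Cd79a did not pass the test and Ebf1 was too dim to be tested.

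Of 18 NK and innate lymphoid genes 6 rose, 0 fell and 12 did not pass (7 and 1 adjusted over the list alone, adjusted p = 2.18e-04, and adjusted p = 0.117 with an estimated correlation). Klrk1 rose by at least 21.4-fold, Klrd1 by 51.9-fold and Il2rb by 10.6-fold. Of 20 T-lineage genes 5 rose, such as Cd3g by at least 11.5-fold and Tcf7 by 6.60-fold, and 1 fell (5 and 2 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.4998 with an estimated correlation). Mast-cell and basophil genes had a median of 1.54 with 2 of 14 risen, Hdc by 14.3-fold and Prss34, and 0 fallen (6 and 1 adjusted over the list alone, adjusted p = 0.00183, and adjusted p = 0.551 with an estimated correlation). That list's median, each gene relative to its own mean, was 0.49, -0.22 and 2.24 in B220+ replicates 1 to 3 and -1.45, -0.12 and 0.00 in the control arrays. Fcer1a, a chain of the IgE receptor, read 6.65 ± 2.31. Immediate-early genes shifted up with 3 of 14 risen, Nr4a1 by 7.06-fold, Egr1 by 5.99-fold and Btg2 by 2.28-fold, and 0 fallen (6 and 1 adjusted over the list alone, adjusted p = 2.96e-04, and adjusted p = 0.135 with an estimated correlation). Interferon-response genes shifted up with 3 of 17 risen, such as Ifih1 by 2.42-fold, and 1 fallen, Cxcl10 by 59.3-fold with 1 of 3 B220+ arrays above background (3 and 1 adjusted over the list alone, adjusted p = 0.0139, which was not kept with an estimated correlation).

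Myeloid lists went both ways in B220+ cells and none shifted. Of 20 granulocyte genes 3 rose, the granule protein genes Ngp by 57.8-fold (above background on 1 of 3 control arrays), Camp by 28.7-fold and Fcnb by 7.93-fold, and 4 fell, among them Mmp8 by 36.4-fold (5 and 4 adjusted over the list alone, adjusted p = 0.372). Of 23 monocyte and macrophage genes 1 rose and 5 fell (2 and 7 adjusted over the list alone, adjusted p = 0.505), with C5ar1 lower by at least 5.12-fold and Ms4a6c higher by 12.9-fold. Of 24 myeloid regulators 4 rose, with Klf4 at 8.12-fold and Irf8 at 3.40-fold, and 2 fell, with Fcgr3 at 7.49-fold (4 and 5 adjusted over the list alone, adjusted p = 0.198). Of 17 dendritic-cell genes 3 rose and 2 fell, Batf3 by 25.7-fold (5 and 2 adjusted over the list alone, median -0.12, adjusted p = 0.198), and with the mean of probes that list passed upward (median 0.66, adjusted p = 0.00584). Without control replicate 1 the myeloid regulators and the B-cell activation genes passed upward (adjusted p = 0.0448 each). Of 19 erythroid and megakaryocyte genes 1 rose and 3 fell, Car2 by 5.39-fold (2 and 3 adjusted over the list alone, adjusted p = 0.573). Of 18 plasma-cell genes 2 rose, with Sdc1 at 5.62-fold, and 3 fell, with Fkbp11 at 23.6-fold and Xbp1 at 3.26-fold (3 and 4 adjusted over the list alone, adjusted p = 0.458). Of 23 B-cell activation genes 4 rose, with Ccr7 at 20.9-fold and Cd83 at 81.1-fold (above background on 1 of 3 control arrays), and 1 fell (4 and 4 adjusted over the list alone, adjusted p = 0.198). Of 18 stem and progenitor genes 5 fell, with Hlf at 8.29-fold and Mycn at 9.44-fold, and 1 rose, Flt3 at 4.03-fold, another probe of which read -0.21 (1 and 7 adjusted over the list alone, adjusted p = 0.198). That list's median was -0.48, and -0.10 within slide 1, which held all B220+ arrays and 1 control array. Of 23 cell-cycle genes 0 passed, also when adjusted over the list alone (adjusted p = 0.497). Median, mean and test differed in sign for the B-cell activation, myeloid-regulator, granulocyte, dendritic and erythroid lists.

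All B220+ arrays lay on slide 1 with control replicate 1. With the slide as a block 1548 genes passed (695 higher, 853 lower), and the NK median was 0.99, the mast-cell one 2.42, the interferon one 0.93, the T-lineage one 0.24 and the heme one -0.84, against 0.26, 1.54, 0.60, 0.08 and -1.26 without it. Slide 1 alone, with 3 arrays against 1, called 0 genes (limma, 1998 at an unadjusted p under 0.05). The count was 1035 without control replicate 2, 1152 without control replicate 3, 1261 without B220+ replicate 2 and 1357 on the arrays numbered 1 and 2 alone. The T-lineage list lost its call with quantile normalization (adjusted p = 0.0537), with a filter on all arrays (0.297) and on the arrays numbered 1 and 2 alone (0.116), where the mast-cell list had 0.0606; T-lineage and mast-cell lists lost it without B220+ replicate 3 (0.115 and 0.0943), and the interferon list without control replicate 2 (0.0657).

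The second B220+ comparison asked how B220+ cells differed from Bach2-vector MPPs that had not passed through B-lineage culture. Dntt rose 114-fold, Ly6d 77.7-fold, Blnk 24.1-fold and Spib 14.3-fold, and Prg2 rose 591-fold, Prss34 98.9-fold and the neutrophil granule genes Ngp 77.6-fold (above background on 1 of 3 Bach2-vector arrays) and Camp 59.7-fold. Clca1, Khdc1a and Gbp2, which had risen with the Bach2 vector, fell by at least 367-fold, by 93.2-fold (Khdc1a above background on 1 of 3 B220+ arrays) and by 10.6-fold, and Thbs1, which had fallen with it, rose 126-fold. Both comparisons use the same Bach2-vector arrays. In all, 1047 of 16987 genes passed, 341 higher and 706 lower in B220+ cells, of which 333 and 681 by at least 2-fold. With quantile normalization the numbers were 462 higher and 600 lower, and the median over all genes moved from -0.25 to -0.06.

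Cd2 changed by log2 10.32 ± 0.80 (adjusted p = 3.75e-04, above background on 1 of 3 Bach2-vector arrays), Dntt by 6.83 ± 0.25 (adjusted p = 8.27e-06). The lectin gene Clec4b2 rose by 6.97 ± 0.81 and Dscam by 5.97 ± 0.94 (above background on 1 of 3 Bach2-vector arrays), and Slc16a14 rose at least 45.5-fold. Hic1 fell by 9.51 ± 0.49 (adjusted p = 6.69e-05), and the serine protease inhibitor gene Spint1 fell by 7.21 ± 0.67. The chemokine Ccl17 fell by 7.05 ± 1.15 (adjusted p = 0.00892). Pdpn fell by 7.16 ± 0.98 and Asb2 fell by 6.64 ± 0.87, both above background on 1 of 3 B220+ arrays, and Aldh1a3, a retinoic acid-making enzyme, fell by 6.39 ± 1.13. Speer6-ps1 was lower by at least 45.0-fold.

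Of 26 early B-lineage genes 6 rose, 1 fell and 19 did not pass (7 and 2 adjusted over the list alone, median 0.34, adjusted p = 4.21e-05, and adjusted p = 0.262 with an estimated correlation). Of 19 mature B-cell genes 4 rose, with H2-Ob at 5.86-fold and Bank1 at 8.68-fold, and 2 fell, with Tnfrsf13c at 10.0-fold (5 and 2 adjusted over the list alone, adjusted p = 0.00135, and adjusted p = 0.262 with an estimated correlation). Granulocyte genes shifted up with 4 of 20 risen, Fcnb by 22.0-fold and Chil3 by 44.0-fold beside Ngp and Camp, and 2 fallen (7 and 3 adjusted over the list alone, adjusted p = 4.58e-05, and adjusted p = 0.262 with an estimated correlation). Of 24 myeloid regulators and receptors 5 rose, with Klf4 at 16.5-fold, the macrophage growth factor receptor gene Csf1r at 10.4-fold and Il6ra at 4.59-fold, and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 1.17e-04, and adjusted p = 0.262 with an estimated correlation). Mast-cell and basophil genes shifted up with 2 of 14 risen and 0 fallen (5 and 0 adjusted over the list alone, adjusted p = 6.86e-04, and adjusted p = 0.421 with an estimated correlation). Immediate-early genes shifted up with Nr4a1 risen by 2.07 ± 0.36 and 0 of 14 fallen (5 and 0 adjusted over the list alone, adjusted p = 0.00399, and adjusted p = 0.262 with an estimated correlation). Of 18 NK and innate lymphoid genes 4 rose, with Klrk1 at least 17.3-fold higher and Il18rap 5.42-fold, and 0 fell (4 and 2 adjusted over the list alone, adjusted p = 0.0468, and adjusted p = 0.344 with an estimated correlation). The NK list's median was -0.18, with 8 genes higher and 10 lower, its mean was 0.33, and the median over all genes was -0.25. Its upward call thus does not mean that most of the list rose. With the slide as a block the NK median was 0.33 (adjusted p = 0.00786), and within slide 1 it was 0.49.

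Of 17 dendritic-cell genes 0 rose and 4 fell, H2-Ab1 by 4.00-fold, H2-Aa by 4.01-fold, H2-Eb1 by 3.28-fold and Batf3 by 34.2-fold (1 and 5 adjusted over the list alone, adjusted p = 0.672). With the slide as a block 1 of the list rose and 2 fell (adjusted p = 0.517), and within slide 1 its median was 0.18. Of 17 interferon-response genes 0 rose and 2 fell, Gbp2 and Cxcl10 by 25.2-fold with 1 of 3 B220+ arrays above background (0 and 3 adjusted over the list alone, adjusted p = 0.0905). That list passed downward with all 21 arrays in 1 fit (adjusted p = 0.0101), normexp (0.0254), quantile normalization (0.0391) and no filter (0.0468), and without Bach2-vector replicate 2 (0.0158) or B220+ replicate 2 (0.0455). Of 18 stem and progenitor genes 0 rose and 3 fell, with Mycn at 13.2-fold (0 and 6 adjusted over the list alone, adjusted p = 0.0837), and that list passed downward with the mean of probes (0.0163), all 21 arrays in 1 fit (0.0275), normexp (0.0300) and no filter (0.0448). Of 18 plasma-cell genes 1 rose, Sdc1 by 7.69-fold, and 3 fell (1 and 6 adjusted over the list alone, adjusted p = 0.226). Of 23 monocyte and macrophage genes 2 rose, with F13a1 at 49.0-fold, and 0 fell (4 and 1 adjusted over the list alone, adjusted p = 0.126, and 0.0142 upward without Bach2-vector replicate 1). Of 19 erythroid genes 2 rose and 3 fell, with Car2 at 10.2-fold (2 and 3 adjusted over the list alone, adjusted p = 0.758). Of 20 T-lineage genes 3 rose and 1 fell (3 and 4 adjusted over the list alone, adjusted p = 0.218). Of 23 B-cell activation genes 1 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.653). Of 25 heme, iron and oxidative-stress genes Srxn1 fell 4.01-fold and 0 rose (0 and 1 adjusted over the list alone, adjusted p = 0.440). Of 23 cell-cycle genes 0 passed, also when adjusted over the list alone (adjusted p = 0.414). Median, mean and test differed in sign for the B-cell activation, monocyte and NK lists. With the slide as a block 709 genes passed (302 higher, 407 lower), and the mature B, myeloid-regulator and immediate-early lists had an adjusted p of 0.0532 each. With it the early B median was 0.64 (6 risen, 0 fallen), the granulocyte one 0.38 (4 risen, 0 fallen, adjusted p = 0.0210), the mast-cell one 1.57, the mature B one 0.40 and the myeloid-regulator one 0.16, against 0.34, 0.90, 0.59, 0.86 and 0.46 without it. On its own slide 1 called 0 genes (limma, 1373 at an unadjusted p under 0.05). The count was 443 and 472 without Bach2-vector replicates 3 and 2, 543 and 609 without B220+ replicates 2 and 1, 1706 without B220+ replicate 3 and 460 on the arrays numbered 1 and 2 alone. Without B220+ replicate 3 the mature B (adjusted p = 0.0697), NK (0.240), mast-cell (0.149) and immediate-early lists (0.183) did not pass. The NK list did not with quantile normalization (0.110), normexp (0.0870), a filter on all arrays (0.294), a variance trend (0.0618) or all 21 arrays in 1 fit (0.0510), without Bach2-vector replicate 1 (0.0717) or without B220+ replicate 1 (0.0673). On the arrays numbered 1 and 2 alone the NK (0.239), immediate-early (0.286), mast-cell (0.163) and mature B lists (0.212) did not pass.

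The follicular B-cell comparison asked what the loss of Bach2 does to mature B cells after engagement of their receptor. Bach2KO cells had 65.6-fold more Hmox1 (log2 6.04 ± 0.29, adjusted p = 6.74e-05), at 5.85 ± 0.21 (SD) against -0.18 ± 0.11 in WT cells. Prdm1, which encodes the plasma-cell regulator Blimp-1, rose 30.6-fold and the antibody joining chain gene Jchain 10.8-fold, together with the inhibitory receptor genes Lilrb4a (49.3-fold) and Lilr4b (49.1-fold), the signalling adaptor gene Fcer1g (23.1-fold) and the cytokine receptor gene Il2rb (24.6-fold). The complement receptor gene Cr2 fell 4.17-fold and the quiescence factor Klf2 2.71-fold. In all, 355 of 13069 genes passed, 289 higher and 66 lower in Bach2KO cells, each by at least 2-fold, the smallest by 2.55-fold. At an unadjusted p under 0.05 there were 1440 genes where chance gives 653, and 18.7% of genes separated the groups fully, where chance gives 10%. Both chance values take the arrays as unpaired, whereas the replicate numbers were taken to pair them. With the replicate number as a block 2979 genes passed, 1252 higher and 1727 lower, among them all 355, and with the slide as a block 1196 passed, 683 higher and 513 lower.

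Ndrg4 changed by 7.08 ± 0.46 (adjusted p = 1.97e-04, above background on 2 of 3 WT arrays), the prostacyclin receptor gene Ptgir by 6.13 ± 0.60 (above background on 1 of 3 WT arrays) and the G-protein regulator Rgs16 by 5.58 ± 0.33 (adjusted p = 1.57e-04). Plau, urokinase, rose at least 83.9-fold (adjusted p = 6.74e-05), Cdkn2a, a cell-cycle inhibitor locus, at least 22.1-fold (adjusted p = 7.55e-04) and Olfm1 at least 16.1-fold. Beside Bach2, the potassium channel gene Kcnk10 fell by 3.74 ± 0.34 (adjusted p = 8.26e-04), the adaptor Scimp fell by 3.45 ± 0.43 (above background on 1 of 3 Bach2KO arrays), the peptidoglycan sensor Nod1 fell by 3.33 ± 0.34 (adjusted p = 0.00105). Slc9b2 fell by 2.87 ± 0.44, the Notch target Hes5 fell by 2.87 ± 0.40, and Cables1 fell by 2.86 ± 0.39. Igf2bp3, Ackr3 and Nedd4 were lower by at least 5.77-fold, 3.11-fold and 3.01-fold.

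Interferon-response genes were higher in Bach2KO cells in all 16 measured cases, with a median of 1.81 (adjusted p = 1.08e-15, and adjusted p = 0.0577 with an estimated correlation). Of these 6 rose and 10 did not pass, with 10 risen when adjusted over the list alone. Rsad2 rose by at least 4.82-fold, Oasl1 by 9.23-fold, Ifih1 by 5.95-fold and Isg15 by 5.12-fold. Of 22 heme, iron and oxidative-stress genes 5 rose, 0 fell and 17 did not pass (7 and 0 adjusted over the list alone, median 0.52, adjusted p = 5.38e-09, and adjusted p = 0.177 with an estimated correlation). Beside Hmox1, Srxn1 rose 22.4-fold, the quinone reductase gene Nqo1 8.71-fold and Me1 at least 2.96-fold. Plasma-cell genes were higher in 15 of 16 cases, with 3 risen, Prdm1, Jchain and Ell2, the last by 3.81-fold, and 6 when adjusted over the list alone (adjusted p = 3.58e-08, and adjusted p = 0.0980 with an estimated correlation). Of 12 NK and innate lymphoid genes 4 rose, Il2rb, the chemokine Ccl5 by 10.3-fold, the death ligand gene Fasl by 7.93-fold and Nfil3 by 3.56-fold, and 6 when adjusted over the list alone (adjusted p = 4.67e-10, and 0.0404 with an estimated correlation). It was the only list of this comparison kept by that test. Dendritic-cell genes were higher in all 13 cases, with Ccr9 risen 14.7-fold and Irf7 3.44-fold, and 6 risen when adjusted over the list alone (adjusted p = 4.67e-10, and adjusted p = 0.0610 with an estimated correlation). Of 15 T-lineage genes Thy1 rose 3.33-fold and Cd5 by 1.63 ± 0.32, 0 fell, and 6 rose when adjusted over the list alone (adjusted p = 1.76e-05, and adjusted p = 0.0980 with an estimated correlation).

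Granulocyte genes had a median of 2.67 with 12 of 13 higher (adjusted p = 1.16e-09, and adjusted p = 0.179 with an estimated correlation). Over the whole list 0 passed (limma, 1440 genes of all tested at an unadjusted p under 0.05), and 8 rose when adjusted over the list alone. S100a9 read 3.23 ± 0.97, Ltf 3.02 ± 0.89, Camp 2.85 ± 0.80 and Lcn2 1.73 ± 0.45. The median of the 12 granulocyte genes measured on every array, each relative to its own mean, was -3.29, -0.11 and -0.82 in WT replicates 1 to 3 and -0.20, 2.08 and 1.99 in Bach2KO. Of 21 myeloid regulators and receptors 4 rose, with Cebpd at least 5.91-fold higher and Cebpb 3.50-fold, beside Fcer1g and Il3ra, and 0 fell (4 and 2 adjusted over the list alone, adjusted p = 0.00852, and adjusted p = 0.177 with an estimated correlation). Of 15 monocyte and macrophage genes 2 rose, the galectin gene Lgals3 by 13.5-fold and Ccl9 by at least 13.3-fold, and 0 fell (7 and 2 adjusted over the list alone, adjusted p = 3.11e-04, and adjusted p = 0.0610 with an estimated correlation). Of 13 erythroid and megakaryocyte genes 4 rose, with Alas2, the first enzyme of heme synthesis in red cells, at 15.2-fold (above background on 1 of 3 WT arrays), the globin gene Hba-a1 at 13.3-fold and Pf4 at least 4.12-fold, and 0 fell (6 and 1 adjusted over the list alone, adjusted p = 9.66e-06, and adjusted p = 0.0577 with an estimated correlation). Of 5 mast-cell and basophil genes Il6 rose 4.98-fold, also when adjusted over the list alone (adjusted p = 0.00852, and adjusted p = 0.0980 with an estimated correlation). The labels name no sort gate for these cells. RNA of other cells was not excluded as a source of the rises in these lists, nor in the NK, T-lineage and dendritic-cell lists.

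Of 20 mature B-cell genes 2 fell, Cr2 and Klf2, 0 rose and 18 did not pass (0 risen and 3 fallen adjusted over the list alone, median -0.32, adjusted p = 0.0227, and adjusted p = 0.429 with an estimated correlation), with Bank1 at -1.35 ± 0.31. Of 23 early B-lineage genes 0 passed and 2 fell when adjusted over the list alone (median -0.34, adjusted p = 0.0415, and adjusted p = 0.587 with an estimated correlation), with Bcl11a at -1.76 ± 0.39 and Sox4 at -1.28 ± 0.30. Cell-cycle genes had a median of 0.23 with Ccnb2, a mitotic cyclin, risen 3.27-fold among 21, also when adjusted over the list alone (adjusted p = 0.0363, and adjusted p = 0.615 with an estimated correlation). Without Bach2KO replicate 3 that median was -0.07 (adjusted p = 0.447), and without WT replicate 2 it was 0.07 (adjusted p = 0.201). Of 22 B-cell activation genes 3 rose, Ccl3 by 8.50-fold, Ccl4 by 4.44-fold and Il10 by at least 3.57-fold, and 1 fell, Ccr7 by 3.12-fold (4 and 8 adjusted over the list alone, adjusted p = 0.399, and 0.0446 without the filter). Of 9 stem and progenitor genes Ly6a rose 9.02-fold and Flt3 fell 3.20-fold, also when adjusted over the list alone (adjusted p = 0.529), and median, mean and test of that list differed in sign. Of 14 immediate-early genes Ier3 rose 6.44-fold and Atf3 12.5-fold, 0 fell, and 2 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0549, and 0.0476 with the median of detected probes).

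With the replicate number as a block 12 of the 13 granulocyte genes rose, S100a9 with an adjusted p of 5.21e-07, Ltf of 4.86e-07, Camp of 1.79e-07 and Lcn2 of 1.87e-05. Lyz2 (1.43e-07), Cd14 (6.52e-05), Batf3 (1.7e-05), Itgax (4.79e-04), Cd28 (2.03e-04) and Mki67 (6.89e-04) rose in that fit, and Bcl11a (2.24e-05), Sox4 (3.61e-04), Bank1 (2.18e-04) and Nr4a1 (1.35e-05) fell. Early B-lineage genes then numbered 2 risen and 10 fallen, mature B-cell genes 3 and 7, B-cell activation genes 6 and 10, plasma-cell genes 8 and 0, interferon-response genes 12 and 0, heme genes 10 and 1, monocyte genes 8 and 3, dendritic-cell genes 9 and 0, NK genes 7 and 0, T-lineage genes 8 and 0, erythroid genes 7 and 1 and cell-cycle genes 10 and 4.

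Both slides held both genotypes, with granulocyte medians of 2.73 and 2.11 within slides 1 and 2, interferon medians of 1.68 and 1.79, heme medians of 0.66 and 0.62, plasma-cell medians of 0.73 and 0.52 and mature B medians of -0.55 and -0.27. With the replicate block the early B and mature B lists had an adjusted p of 0.0606 and 0.103, with the slide block these were 0.0730 and 0.112 and the cell-cycle list 0.0588, and with quantile normalization the early B, mature B and mast-cell lists had 0.111, 0.0933 and 0.0638. With a filter on all arrays the monocyte list lost its call (median 0.08, adjusted p = 0.101), as did the early B list (adjusted p = 0.101). With all 21 arrays in 1 fit the early B and mature B lists had 0.117 and 0.145, on slide 2 alone the early B, mature B and cell-cycle lists had 0.163, 0.286 and 0.135, and without the filter the cell-cycle list had 0.165. The count was 158 without Bach2KO replicate 3, 194 without WT replicate 3, 217 without WT replicate 2, and 123 with normexp background correction.

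The 3 experiments were also compared by testing genes that changed in one as a set in another, with the 100 genes of the largest test statistic in each direction for the CLPs, where 1 gene had passed. Of 94 measured genes that tended higher in DD CLPs, 63 were lower with the Bach2 vector in MPPs (adjusted p = 9.81e-06), and 10 fell and 2 rose there. Of 58 measured in follicular B cells 35 were higher in Bach2KO cells (adjusted p = 1.14e-08), and 12 rose and 0 fell. Of 101 genes that fell with the Bach2 vector 68 were higher in DD CLPs (adjusted p = 2.53e-06). Of 171 that rose 99 were lower (adjusted p = 0.00777). Of 86 genes that tended lower in DD CLPs 50 were higher with the Bach2 vector (adjusted p = 0.00777), and 5 rose and 1 fell there. Of 271 that rose in Bach2KO follicular B cells 172 were higher in DD CLPs (adjusted p = 0.00474). The sets lower in DD CLPs and lower in Bach2KO cells did not shift in the other experiment (adjusted p = 0.342 and 0.204). With the replicate number and with the slide as a block, the set lower in DD CLPs had an adjusted p of 0.279 and 0.305 in the MPPs, and the set risen in Bach2KO cells 0.467 and 0.126 in the CLPs. None of the 6 shifts was kept by the test with an estimated correlation, where the adjusted p was 0.153 to 0.611 over the 8 sets. Without WT CLP replicate 1 the set lower in DD CLPs turned in the MPPs (adjusted p = 0.238), the set risen with Bach2 turned in the CLPs (adjusted p = 0.837), and the set higher in DD CLPs lost its shift in the MPPs (adjusted p = 0.395). The set risen with Bach2 also lost its shift in the CLPs without DD replicate 2 (adjusted p = 0.0507) or 3 (0.189), control-vector replicate 1 (0.174) or 2 (0.125), or Bach2-vector replicate 2 (0.0948) or 3 (0.137). The set lower in DD CLPs lost it in the MPPs without DD replicate 1 (0.0942), 2 (0.0507) or 3 (0.293) or control-vector replicate 2 (0.0591), without the filter (0.159) and with all 21 arrays in 1 fit (0.111). The set risen in Bach2KO cells lost it in the CLPs without WT replicate 2 (0.0607) or DD replicate 1 (0.0942). Across genes, which are not independent replicates, Pearson's r and Spearman's rho of the log2 differences were -0.06 and 0.02 between CLPs and MPPs over 16173 genes, and 0.0046 and -0.08 between CLPs and follicular B cells over 12948.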

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

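Except for the fit with the replicate number as a block, which was planned, the tests in this part were chosen only after results were seen, on the data they were chosen from. Signal appeared in probes that no gene symbol could be given to, which the comparisons leave out. Tested by limma in the same way, 22 of 21373 such probes passed between the vectors in MPPs (9 higher, 13 lower), 495 in B220+ cells against control-vector cells (247 higher, 248 lower) and 153 against Bach2-vector cells (73 higher, 80 lower). In Bach2KO follicular B cells 31 of 13676 passed (30 higher, 1 lower), and in CLPs 0 of 20463.

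Granulocyte genes lay higher in Bach2KO follicular B cells by a median of 2.67, and the labels give no sort gate for those cells. A difference between the slides is argued against, since the list lay higher by 2.11 on the slide with the smaller difference. Granulocyte RNA in the preparations may account for part of it and is not settled. The list's genes varied together within groups with an estimated correlation of 0.914, but of 0.242 with the replicate number as a block, where the cell-cycle list had 0.646, so most of it was shared by arrays of 1 number. The list shares 0 of its 21 entries with another list, and 7 were above background on all 3 WT arrays. Its abundant S100a9 read -1.33, 2.55 and 1.69 in WT and 2.77, 4.92 and 4.92 in Bach2KO replicates 1 to 3, and S100a8 -2.89, 1.06 and -0.22 against 0.58, 3.21 and 3.33. The erythroid, NK, T-lineage, dendritic-cell and monocyte lists also lay higher in Bach2KO cells, with medians of 0.68 to 0.95. The early B and mature B lists lay lower, with medians of -0.34 and -0.32. RNA of other cells was not tested for any of these lists. An effect of the genotype on the B cells themselves was not tested and stays open.

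The Y-linked genes were near background in replicate 3 of every MPP group. A single mislabelled array is argued against, since 3 groups showed it. Donor mice of the other sex in that replicate could account for it, as Xist lay at least 2.08 above the other replicates in each group. The labels give no sex, and no biological explanation beyond the sex of the donors was tested.

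In CLPs 1 gene passed. With the replicate number as a block 0 genes passed (limma, 1482 at an unadjusted p under 0.05 against 619 without it and 823 by chance), and the residual SD went from 0.503 to 0.328, so leaving the replicate pairs out of the fit could be part of the reason and is not settled by that 0. A larger spread between CLP arrays might account for part of it and is not settled. Of the follicular B-cell genes 44.8%, 150 of 335, still passed when each was given its CLP standard error. Those genes were picked for passing with their own standard error, so some would be lost even at equal spread. Over the 12948 genes of both experiments the median ratio of CLP to follicular B-cell standard error was 1.11. Whether the double deficiency changes fewer genes in CLPs stays open.

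Chance was tested by splitting the 6 arrays of each comparison in all 10 ways, which cannot give a share under 0.05. The real split called 1 gene in CLPs and the highest other 2, with 2 splits reaching the real count, and the highest among the 4 splits parting 3 pairs was also 2. In the other comparisons 305, 2056, 1047 and 355 genes stood against 0 in every other split (limma), with 1 split, the real one, reaching the count in each. Every other split mixes the groups, so a real difference would add to its spread and lower its count. Those counts of 0 are thus not a chance level. For lists the real and highest other values were 4 and 7 in CLPs, 10 and 8 between the vectors, 8 and 10 and 7 and 7 for the B220+ comparisons, and 14 and 9 in follicular B cells, with 4, 1, 3, 3 and 1 splits reaching the real value. The list counts of mixed splits can hold part of a real difference, so they are not a chance level either.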

How the results depend on the processing

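Some alternatives were added after the data were seen: every probe, slides alone, MPP arrays 1 and 2 alone, and the 6 arrays of the vector comparison alone. Planned ones all ran. Totals of genes and lists not given here stayed within 1.5 times, although numbers higher or lower moved by more, and no named gene reversed. Of the named genes 76 of 82 in CLPs, 39 of 88 between vectors, 10 of 84 and 10 of 87 in the B220+ comparisons and 37 of 92 in follicular B cells never changed their call. Except where a reason is given, the cause was not tested.

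In CLPs the 1 gene became 0 with quantile normalization, both blocks, an adjusted p under 0.01 and every probe, and 8 with all 21 arrays in 1 fit (limma, 633, 1482, 619 and 1473 at an unadjusted p under 0.05 for the zeros). It ranged from 0 to 16 when 1 array was left out: 0 without WT replicate 1, 2 or 3 or DD replicate 3 (1064, 393, 300 and 510 at an unadjusted p under 0.05), and 16 without DD replicate 1. The 4 shifted lists became 2 with quantile normalization and ranged from 0, without WT or DD replicate 1, to 8, without WT replicate 2 or 3, with 7 without DD replicate 3. Leaving out DD replicate 3 brought in mast-cell genes (adjusted p = 1.88e-05), WT replicate 2 mature B genes (0.0253) and DD replicate 2 cell-cycle genes (0.0193). None of the 4 was kept in every alternative.

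Between the vectors the 305 genes became 97 at an adjusted p under 0.01, where a stricter limit lowers the count by construction. They became 163 on arrays 1 and 2 alone and 106 to 199 without 1 array, and 97 were higher on slide 2 alone. Fewer arrays need not lower a count, which rose without B220+ replicate 3 in both B220+ comparisons. The 10 lists ranged from 9 to 12 and 6 were kept in every alternative other than the estimated correlation. B220+ against control-vector cells gave 863 at an adjusted p under 0.01, 1357 on arrays 1 and 2, 0 on slide 1 alone, and 1035 to 2636, the highest without B220+ replicate 3, with 1908 lower without control replicate 1 and 785 without B220+ replicate 1; the 8 lists ranged from 6 to 10. B220+ against Bach2-vector cells gave 356, 460 and 0, and 443 to 1706, the highest without B220+ replicate 3; its 7 lists became 4 with the slide block, 4 on slide 1 alone and 3 on arrays 1 and 2, and ranged from 3, without B220+ replicate 3, to 8. Slide 1 alone holds 1 control or Bach2-vector array, assumed to vary like the others (limma, 1998 and 1373 at an unadjusted p under 0.05).

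In follicular B cells the 355 genes became 123 with normexp, 170 at an adjusted p under 0.01, 2979 with the replicate block and 1196 with the slide block, and ranged from 158, without Bach2KO replicate 3, to 441, without Bach2KO replicate 1. Of these the 66 lower became 27 without the filter, 41 with every probe, 104 with all 21 arrays in 1 fit, 118 on slide 2 alone, 120 without Bach2KO replicate 1 and 35 without WT replicate 1. The 14 lists ranged from 11 to 14. Early B genes lost their call without WT replicate 1 (adjusted p = 0.148), Bach2KO replicate 1 (0.0642) or 3 (0.0750), mature B genes without Bach2KO replicate 1 (0.126), and cell-cycle genes without WT replicate 1 (0.0874) or 2 (0.201) or Bach2KO replicate 1 (0.108) or 3 (0.447).

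With an estimated correlation 0, 1, 1, 0 and 1 lists shifted in the 5 comparisons, and 0 of the sets carried between experiments, of which 3 to 6 shifted without 1 array, 3 without WT CLP replicate 1. There the genes lower in DD CLPs turned in the MPPs, with a camera p of 0.119 (0.00234 to 0.293 without 1 array, limma adjusted p = 0.238), and those risen with Bach2 turned in the CLPs, with 0.718 (from 2.86e-06 up, adjusted p = 0.837).

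The replicate block gave 0 genes in CLPs and 325 between the vectors. With it 34 named genes gained and 5 lost a call and 394 did not change, and no other call of a list or set changed than those printed. In B220+ cells the numbers were not taken to pair the arrays, although replicate 3 lacked Y-linked signal in every MPP group, since not every correlation was over 0.1: they were 0.12, -0.03 and -0.06 with control-vector and 0.08, 0.12 and 0.10 with Bach2-vector cells. With control-vector cells replicate 1 alone correlated best with its own number, with Bach2-vector cells all 3 did, and between the vectors replicate 3 did not (0.30 against 0.31). The block gave 2588 and 1387 genes there, and the NK list 0.0561. Signal was low in the follicular B cells, with 50.9% to 58.8% of spots well above background, and without the filter the median over all genes moved from -0.16 to 0.04.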

Other observations

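The tests in this part were chosen only after results were seen. Genes that fell with the Bach2 vector in MPPs lay higher in Bach2KO follicular B cells: of 60 measured 46 were higher and 14 lower, 19 rose and 2 fell (adjusted p = 9.19e-17, and 0.00845 with an estimated correlation). The overlap of 19 genes stood against 1.27 by chance among 12991 (Fisher's exact test, adjusted p = 3.33e-17). That test takes genes as independent and equally likely to pass, which they need not be. Overlap exceeded its chance value in every pair of directions, with an odds ratio of 22.8 here and 5.41 to 7.04 in the others. The 19 genes included Srxn1 (-4.25 with the vector and 4.49 in Bach2KO cells), Me1 (-5.82 and 3.58), the matrix protein gene Tgfbi (-4.91 and 3.50), Ttc39c (-4.88 and 4.02), the zinc importer Slc39a4 (-4.14 and 3.80), the lectin receptors Clec4d (-3.91 and 3.43) and Clec4e (-2.68 and 4.10), Fosl1 (-3.37 and 2.52), Mocos (-3.01 and 4.74) and Slpi (-2.74 and 3.92), beside Cebpd, Ccl9 and Ell2. These log2 values are not lower bounds. That of Me1 in Bach2KO cells rests on WT signal not well above background on any array. In the same Bach2KO arrays the granulocyte list lay higher by a median of 2.67, and RNA from other cells in them was not excluded.

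In the other direction, 48 of 65 genes that fell in Bach2KO cells were higher with the vector and 17 lower (adjusted p = 4.23e-07, and 0.00731 with an estimated correlation). Scml4 (2.35 and -1.70), Tmcc3 (2.42 and -2.40), Marcks (3.58 and -1.51) and Ccr7 (3.59 and -1.64) rose with the vector and fell in Bach2KO cells, 4 genes where chance gives 0.640 (Fisher's exact test, adjusted p = 0.00510). Genes moved alike as well: 13 rose in both where chance gives 2.72 (adjusted p = 6.49e-06) and 2, Nod1 and Rab34, fell in both where chance gives 0.300 (adjusted p = 0.0362). Sets of genes that rose with the vector (adjusted p = 0.219) or in Bach2KO cells (adjusted p = 0.134) did not shift in the other experiment. Across 12991 genes, which are not independent replicates, Pearson's r was -0.11 and Spearman's rho -0.07.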
